A study of Homo sapiens with 8 samples.

How the data were processed

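RNA from OCI-AML5, an established human acute myeloid leukemia cell line that grows in suspension, was measured by RNA sequencing in 8 libraries. Per the labels' protocols, cells received a lentiviral vector carrying Cas9 and a guide RNA, RNA was extracted by a phenol-chloroform method, and libraries were made from polyadenylated RNA. There were 4 libraries with control guides (sgControl 1 to 4) and 4 libraries with guides against CEBPD (sgCEBPD 1 to 4), and each library held a different guide. The values deposited by the authors were raw read counts per gene, not normalised. Per the submitters' processing notes, FastQC, HISAT2 and DESeq2 were used with the human build hg38, without roles or versions. The counting tool, its strand setting and the annotation were not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be assigned with certainty.

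The table had 23562 rows, and the lowest row total was 4 counts. Of these rows, 116 repeated a symbol and were kept as separate rows. Library totals lay between 10217751 and 11521209 counts. Columns were matched to libraries by the library names in the labels. The guide number was not used to pair libraries.

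Counts were tested in R 4.3.3 with edgeR 4.0.16: genes were filtered by filterByExpr with the group, library sizes were scaled by TMM, and a robust quasi-likelihood test was fitted with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM (counts scaled to the library size) are TMM-normalised, except where the text says CPM of library totals, log2 fold changes are sgCEBPD over sgControl, and the standard error (SE) is the absolute log2 fold change divided by the square root of F. Because each library was a different guide, the spread within a group includes the spread between guides. No label says whether a transduction was repeated, so p-values measure only the spread between these libraries. Principal components were computed on log2 CPM with a prior count of 2. The CEBPD level was also compared by an exact two-sided permutation test over 70 assignments.

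Before the data were examined, 37 gene lists were fixed. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. Camera with an estimated correlation and fry were computed beside it. The count of changed members is given with p-values adjusted over all genes and adjusted over the list alone.

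The rule for named genes was also fixed beforehand. It took CEBPD. It took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 2 CPM and no overlap between groups, leaving out clone and accession names. With fewer than 5 such genes in a direction, the genes with the lowest unadjusted p filled up to 5. It took up to 3 changed members, those with the lowest p, of the lists past camera (at most 10 lists), or of the 5 lists with the lowest p if fewer than 5 passed. It also took the tested neighbours of CEBPD and the tested genes of the fixed C/EBP family list.

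Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors (RLE) or library totals in edgeR, no filter, a mean of at least 5 CPM, each library left out, the guide number as a block, 1 surrogate variable from sva 3.50.0, an adjusted p under 0.01 and a tested fold over 1.2. After seeing the data, voom with library quality weights and a second set of results without sgCEBPD 3 were added. The rule for named genes, the list tests and the alternatives were repeated on those 7 libraries.

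The functions were tested on simulated counts with the real means and library totals, the dispersions that edgeR estimated, and some genes changed. For the comparison of 8 libraries, 13630 genes were tested in the simulated table, and edgeR recovered 13.8% of genes changed 1.5-fold, 56.1% of those changed 2-fold and 87.5% of those changed 4-fold. Of its calls there, 7.27% were unchanged genes, against 26.3% for DESeq2. For the comparison of 7 libraries, with 13824 genes, the recovered shares were 56.1%, 74.2% and 96.9%, and 10.2% of edgeR's calls and 16.3% of DESeq2's calls were unchanged genes. A list shifted 1.5-fold was called by camera in both simulated comparisons, with the preset and with the estimated correlation. Simulated genes were drawn independently, so this does not show how camera fares where list members move together. Simulated libraries differed only in total and group, so a library that stands apart was not covered. Each comparison was a single draw from edgeR's own dispersions, which may favour edgeR, so these shares do not rank the tools.

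Gene positions were taken from GENCODE release 29 on GRCh38, the same build as hg38, by matching symbols, and 95.7% of rows matched.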

Results

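The experiment asked how transcripts differ when guides against CEBPD replace control guides in OCI-AML5 cells. CEBPD encodes C/EBP delta, a transcription factor of the CCAAT/enhancer-binding protein family. Gene counts were compared between 4 sgCEBPD and 4 sgControl libraries. Library totals were 11298795, 10217751, 10919798 and 10901777 counts for sgControl 1 to 4, and 10755734, 10556847, 10712069 and 11521209 counts for sgCEBPD 1 to 4.

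CEBPD transcript was near the control level in 2 of the 4 sgCEBPD libraries. It stood at 107 CPM in sgCEBPD 1, which was 51.6% of the control mean, and at 164 CPM (79.3%) in sgCEBPD 4. In sgCEBPD 2 it stood at 209 CPM, just above the control mean, and in sgCEBPD 3 at 195 CPM (94.2%). The controls had 216, 204, 205 and 202 CPM. The group means were 169 ± 45.5 CPM for sgCEBPD and 207 ± 6.46 CPM for sgControl (SD, n = 4 each). The log2 fold change was -0.29 (SE 0.18), with an adjusted p of 0.551 in edgeR's quasi-likelihood test. The exact two-sided permutation test gave p = 0.114, where the smallest p the design allows is 0.0286. Without sgCEBPD 1 the log2 fold change was -0.12. CEBPD lies on chromosome 8 from 47736909 to 47739086 on the minus strand (GRCh38) and has 1 exon. A small insertion or deletion made by Cas9 can leave the transcript in place, so this level measures neither the edit nor the protein and does not check the labels.

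**Figure D1:**
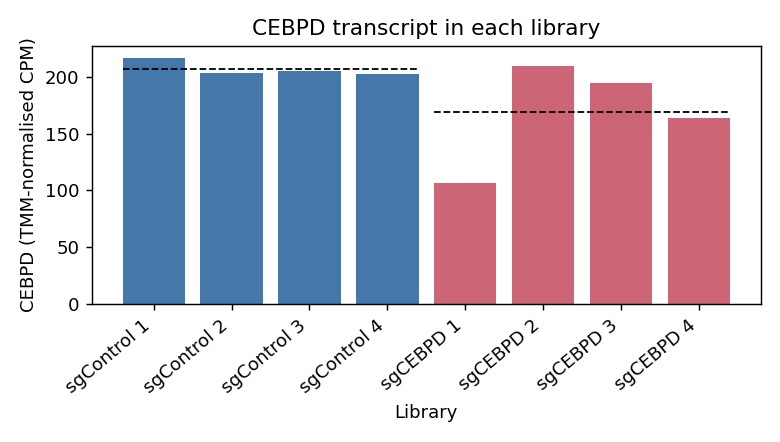
CEBPD transcript in TMM-normalised CPM (vertical axis) in each of the 8 libraries (horizontal axis), with sgControl in blue, sgCEBPD in red and a dashed line at each group mean. The 4 controls lie between 202 and 216 CPM, and sgCEBPD 1 lies lowest at 107 CPM.

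The library sgCEBPD 3 stood apart from the other 7. On the first principal component, which held 56.7% of the variance, it scored 96.0, and the other libraries scored between -21.3 and 0.57. Its correlations with other libraries, across genes, were 0.912 to 0.931, against 0.972 to 0.989 among the other 7. Its monocyte and macrophage genes were high, such as ITGAM (CD11b) at 210.4 CPM against 4.00 to 21.3 CPM elsewhere. KIT, a receptor of progenitor cells, was at 2.46 CPM against 18.1 to 51.9 CPM. The fixed stem and progenitor list (22 tested) was less far out than KIT. Against the mean of sgCEBPD 1, 2 and 4, its median log2 ratio was -0.22, at the 6.58th percentile of random lists matched on expression. The fixed LSC17 list of leukemia stem cell genes (12 tested) lay lower, at -0.55 (0.1th percentile). The second component, with 14.4% of the variance, set the controls (5.60 to 21.6) apart from sgCEBPD 1, 2 and 4 (-34.3 to -11.7), and sgCEBPD 3 scored 7.47. Because component scores are uncorrelated by construction and sgCEBPD 3 dominated the first, its second score does not show which group it resembles. ITGAM and KIT were picked after their values were seen.

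**Figure D2:**
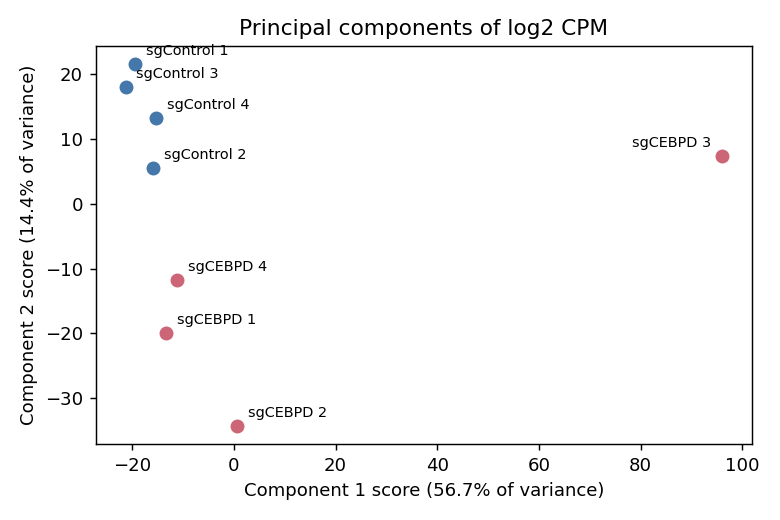
Scores of the 8 libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 CPM, with sgControl in blue and sgCEBPD in red. sgCEBPD 3 lies at 96.0 on the first component, away from the other 7 libraries.

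Across all 8 libraries, 10 genes fell and 1 rose in the sgCEBPD group. PADI2, an enzyme that converts arginine in proteins to citrulline, fell from 9.14 ± 1.64 to 1.39 ± 0.156 CPM (SD, n = 4 each; log2 fold change -2.71, SE 0.20, adjusted p = 0.0052 in edgeR). HAL, which starts the breakdown of histidine, fell from 22.6 ± 4.09 to 4.27 ± 1.01 CPM (log2 fold change -2.40). CTSG, a serine protease of neutrophil primary granules, fell from 31.3 ± 7.49 to 6.37 ± 1.61 CPM (log2 fold change -2.29). PDE7B, a phosphodiesterase that degrades cyclic AMP, fell with a log2 fold change of -1.96, and GPR153, an orphan receptor, with one of -1.74. The mitochondrial acyl-CoA synthetases ACSM3 and ACSS3 fell with log2 fold changes of -1.48 (SE 0.17) and -1.17 (SE 0.13). In each of these 7 genes all 4 sgCEBPD libraries, sgCEBPD 3 included, lay below all 4 controls. The gene that rose, EPHB6, a receptor of the ephrin family, went from 0.962 to 2.96 CPM. EPHB6 lay under the minimum of 2 CPM of the naming rule and was named after its values were seen.

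Of the 13838 genes tested, 1576 had an unadjusted p under 0.05, where 692 were expected by chance. All 11 called genes changed over 2-fold and showed no overlap between the groups, which 2.86% of assignments of 8 values give by chance for a gene not picked by its p. These genes were picked on the same groups, so their lack of overlap is no separate evidence. No gene higher in sgCEBPD met the naming rule past the test, since EPHB6 lay under its minimum. The genes that filled that direction by lowest p, none of them past the test, were MVP (10.4 against 3.22 CPM, adjusted p = 0.0705), ADRA2C (9.81 against 0.951 CPM), DHRS9 (138 against 89.9 CPM), IL13RA1 (50.9 against 28.9 CPM) and ADAM28 (16.5 against 2.15 CPM). The count was 283 without sgCEBPD 3, 0 without sgCEBPD 2 (edgeR, with 1345 genes at an unadjusted p under 0.05), 6 without sgCEBPD 1 or sgControl 2, and 1 without sgControl 1, sgControl 3 or sgControl 4. DESeq2 called 292 genes, voom with quality weights 223, the fit with 1 surrogate variable 302 and the fit with no filter 20, while the fit with the guide number as a replicate block and an adjusted p under 0.01 called 1 each. Of the 11 genes, 4 were among the 6 called without sgCEBPD 1, and 4 among the 10 called without sgCEBPD 4.

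Without sgCEBPD 3, a choice made after seeing the data, 99 genes rose and 184 fell among the 14047 tested, and all 11 genes above were among them. Among genes that met the naming rule (a mean of at least 2 CPM and no overlap), the largest rise was in ADRA2C, an adrenergic receptor, from 0.957 ± 0.671 CPM (SD, n = 4) to 8.98 ± 3.82 CPM (SD, n = 3), a log2 fold change of 3.22 (SE 0.52, adjusted p = 0.0297 in edgeR). S100A8, a calcium-binding protein abundant in mature neutrophils and monocytes, rose from 1.04 to 8.19 CPM, and the library left out had 0.0982 CPM. SPP1 (osteopontin) rose from 3.46 to 20.3 CPM and A2M, a protease inhibitor, from 0.788 to 5.03 CPM. In the library left out, SPP1 stood at 162 CPM and A2M at 69.2 CPM. Other large rises were in ARHGEF10L (log2 fold change 3.03), ADAM28 (2.59), ZNF467 (1.88), MVP (1.61), KYNU (1.58) and ATP1B1 (1.52).

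Among genes that met the naming rule, the largest fall was in BPI, a bactericidal protein of neutrophil primary granules, from 4.75 ± 2.04 to 0.147 ± 0.18 CPM (log2 fold change -4.86, SE 0.63), and the library left out had 17.6 CPM. ROS1 and LTK, both receptor tyrosine kinases, fell with log2 fold changes of -3.29 and -2.44. ELFN2 fell with one of -3.61, in 1 of the rows that share its symbol. PADI2 (-2.64), HAL (-2.55), ADGRG3 (-2.49), CILP2 (-2.38), CTSG (-2.17) and PDE7B (-2.06) completed the 10 largest falls under the rule. In ROS1 and ADGRG3, sgCEBPD 3 stood at 5.01 and 4.81 CPM, within the range of the controls. CSF3R, the receptor of granulocyte colony-stimulating factor, fell from 302 to 196 CPM, and CXCR2, a chemokine receptor of neutrophils, from 52.6 to 41.6 CPM. In sgCEBPD 3 they stood at 418 and 53.3 CPM. TLR4, the receptor of lipopolysaccharide, fell from 98.4 to 72.1 CPM, with 59.1 CPM in sgCEBPD 3. CSF3R, CXCR2 and TLR4 are changed members of fixed lists outside the naming rule and were picked after their values were seen.

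All 283 genes showed no overlap between the groups, which 5.71% of assignments of 7 values give by chance for a gene not picked by its p, and is again no separate evidence. Of the 283, 82 changed over 2-fold, 30 higher and 52 lower. The count was 66 without sgControl 1, 142 without sgControl 3, 152 without sgControl 4, 139 without sgCEBPD 1 and 146 without sgCEBPD 2. DESeq2 called 596 genes, and 109 were called with 1 surrogate variable. A2M, ATP1B1, BPI, PADI2, HAL, CILP2, CTSG and PDE7B stayed at an adjusted p under 0.05 in every 7-library refit that tested them. These refits were other tools, scalings and filters, the block, the surrogate variable and libraries left out. At an adjusted p under 0.01, ATP1B1 (0.0149) lost the call. The other genes that the rule named past the threshold here, list members included, lost the call in at least 1 refit. With all 8 libraries, BPI (adjusted p = 0.984 in edgeR), ATP1B1 (0.272), A2M (0.249) and CILP2 (0.202) did not pass.

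**Figure D3:**
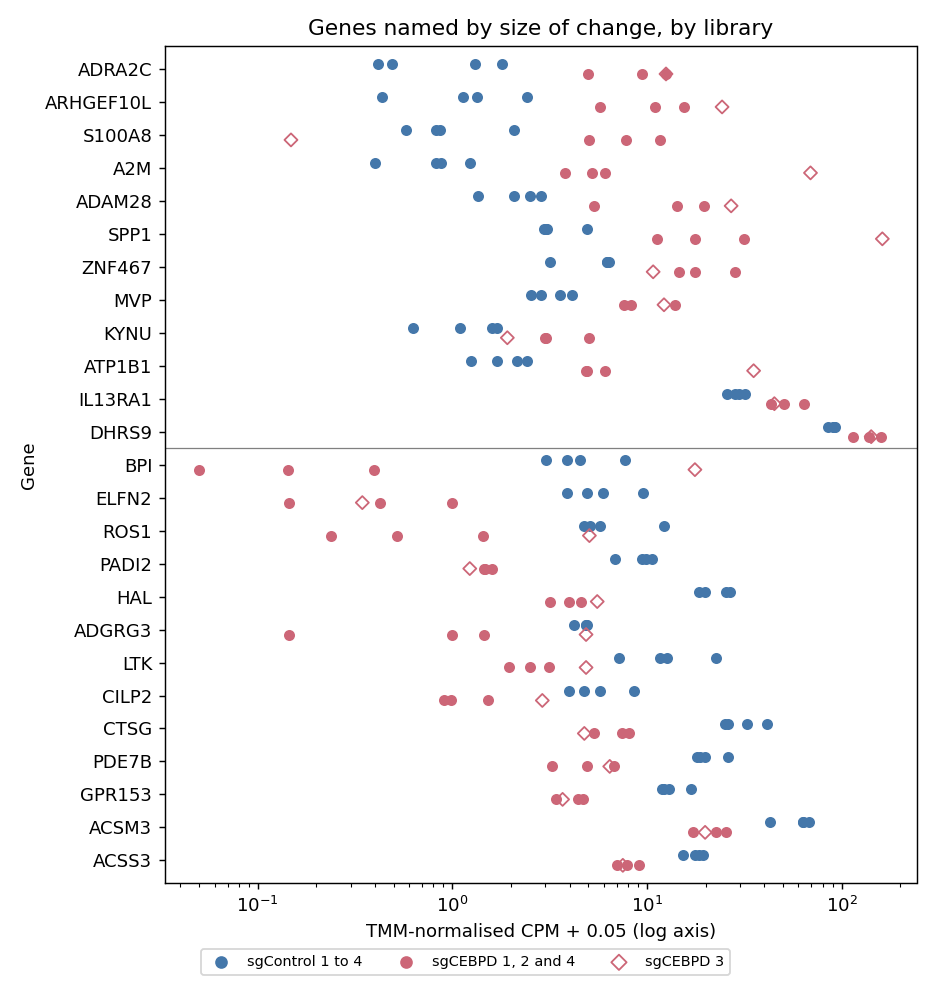
TMM-normalised CPM plus 0.05 on a log axis (horizontal) in each library for the genes named by size of change (vertical axis), higher in sgCEBPD above the grey line and lower below it. Blue points are controls, red points are sgCEBPD 1, 2 and 4, and open diamonds are sgCEBPD 3, which lies with the other sgCEBPD libraries for PADI2, HAL and CTSG but not for S100A8 or BPI.

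Of 16 neutrophil primary granule genes fixed, 12 were tested, and 10 had negative log2 fold changes over all 8 libraries (camera adjusted p = 0.00088). With an estimated correlation the adjusted p was 0.625, and 0.648 without sgCEBPD 3. With 8 libraries 1 member (CTSG) fell, or 3 adjusted over the list alone. Without sgCEBPD 3, all 12 were negative and CTSG and BPI fell, or 4 members adjusted over the list alone. MPO, the myeloperoxidase, had 17.9 CPM in controls and 15.7 CPM in the 3 sgCEBPD libraries and did not pass. In sgCEBPD 3, BPI stood at 17.6 CPM, above every control.

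Interferon-stimulated genes (46 fixed, 42 tested) had positive log2 fold changes in 36 members over all 8 libraries, with a median log2 fold change of 0.41 (camera adjusted p = 9.46e-06). With an estimated correlation the adjusted p was 0.625, and 0.648 without sgCEBPD 3. No member passed over all genes, and 7 rose and 1 fell adjusted over the list alone. Without sgCEBPD 3, the median was 0.35. SP110 (16.3 to 22.0 CPM) and GBP4 (8.72 to 17.7 CPM) then rose and HERC5, a ligase for the ubiquitin-like ISG15, fell from 26.9 to 17.3 CPM. Adjusted over the list alone, 10 rose and 2 fell. GBP4 stood at 3.44 CPM in sgCEBPD 3, below the controls.

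Genes of the integrated stress and unfolded protein responses (33 fixed and tested) had positive log2 fold changes in 30 members, with a median of 0.35 (camera adjusted p = 3.84e-06, and adjusted p = 0.625 with an estimated correlation). Hypoxia and glycolysis genes (34 fixed, 33 tested) were positive in 31, with a median of 0.23 (camera adjusted p = 9.46e-06, and adjusted p = 0.650 with an estimated correlation). No member of either list passed over all genes with 8 libraries. Adjusted over the list alone, 7 stress genes and 0 hypoxia and glycolysis genes rose. Without sgCEBPD 3 the medians were 0.13 and 0.08, with adjusted p = 0.941 and 0.648 with an estimated correlation. Adjusted over the list alone, 8 stress genes rose and 4 fell, and 4 hypoxia and glycolysis genes rose and 1 fell. MTHFD2, a mitochondrial folate enzyme, then rose from 134 to 169 CPM, HERPUD1, a gene of endoplasmic reticulum stress, from 47.2 to 77.2 CPM, and CHAC1, a glutathione-degrading enzyme, from 4.37 to 11.7 CPM. PFKP, a phosphofructokinase, rose from 259 to 322 CPM and PDK1, a kinase of pyruvate dehydrogenase, from 67.6 to 80.4 CPM. Of the 7 libraries, leaving out sgControl 3 or sgCEBPD 4 also ended the preset call of stress genes (adjusted p = 0.0936 and 0.125), and leaving out sgCEBPD 4 that of hypoxia and glycolysis genes (0.0604).

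Monocyte and macrophage genes (42 fixed, 23 tested) were positive in 18 members over all 8 libraries, with a median log2 fold change of 1.12 (camera adjusted p = 0.00173). With an estimated correlation the adjusted p was 0.625, and 0.941 without sgCEBPD 3. No member passed over all genes, and 4 rose adjusted over the list alone. Without sgCEBPD 3 the median was 0.28. TYROBP, a signalling adaptor of myeloid receptors, then rose from 5.70 to 13.8 CPM, and 4 members again rose adjusted over the list alone. In sgCEBPD 3, TYROBP stood at 62.4 CPM. Of the 7 libraries, leaving out sgControl 1, sgControl 3 or sgCEBPD 2 ended the preset call (adjusted p = 0.0779, 0.151 and 0.209), as did DESeq2 size factors and the filter at a mean of 5 CPM.

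Genes linked to C/EBP delta before the data were examined (23 fixed, 15 tested) were not called by camera in either comparison. Over 8 libraries no member passed, 1 fell adjusted over the list alone, and the camera adjusted p was 0.950, with a positive median (0.04) and mean (0.40) beside a test statistic in the lower direction. Without sgCEBPD 3, TLR4 fell, 10 of 15 log2 fold changes were negative, the median was -0.08 and the camera adjusted p was 0.273. The mixed fry test, which counts change in either direction, gave adjusted p = 0.324 with 8 libraries and 0.00184 without sgCEBPD 3. In the latter, 20 of 33 lists passed the mixed test. In sgCEBPD 3 against the mean of sgCEBPD 1, 2 and 4, the median log2 ratio of this list was 0.76. Late neutrophil maturation genes (36 fixed, 14 tested) went both ways without sgCEBPD 3: S100A8 rose, and CSF3R and CXCR2 fell. Adjusted over the list alone, 2 rose and 4 fell. The camera adjusted p, which measures change in 1 direction, was 0.854, and the mixed fry test gave adjusted p = 0.00012.

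In all, camera with the preset correlation called 10 of 32 lists with 8 libraries. Beside the 5 described above, these were apoptosis regulators and cholesterol synthesis (higher), and G1/S, MYC and its targets and heat shock genes (lower). With an estimated correlation their adjusted p was 0.625 for apoptosis regulators and 0.651 for the other 4. Heat shock and cholesterol synthesis also lost the call without sgControl 1 (adjusted p = 0.0819 for both) and without sgCEBPD 2 (0.0993 and 0.0766), and cholesterol synthesis without sgControl 3 (0.107). All 5 calls ended without sgCEBPD 3 (lowest adjusted p 0.0594), where 5 of 33 lists were called. The G1/S list, for example, had a median of -0.14 with 40 of 42 members negative, and of -0.01 with 22 negative without sgCEBPD 3. In camera with an estimated correlation, 0 lists passed in either comparison. With fry, 0 lists moved on balance in 1 direction, and 3 and 20 changed in either direction.

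**Figure D4:**
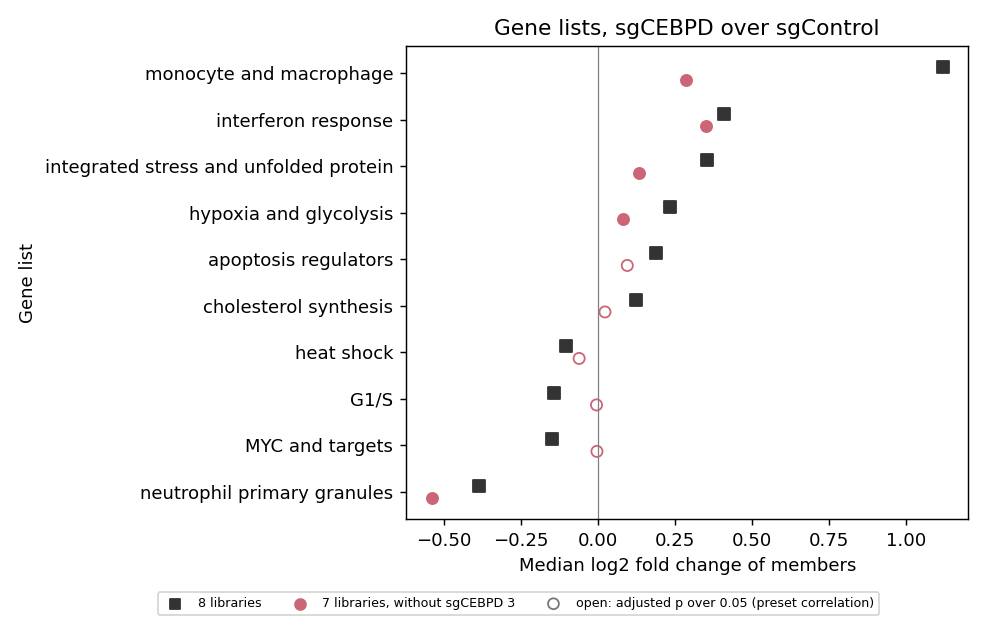
Median log2 fold change of tested members, sgCEBPD over sgControl (horizontal axis), for the 10 gene lists called with 8 libraries (vertical axis). Black squares are 8 libraries and red circles 7 libraries without sgCEBPD 3, open where the adjusted p with the preset correlation was over 0.05, as for G1/S (-0.14 with 8 libraries, -0.01 with 7).

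None of the tested neighbours of CEBPD on chromosome 8 or tested genes of the fixed C/EBP family list passed the edgeR test in either comparison. SPIDR, which acts in DNA repair, had 78.4 against 82.5 CPM, and UBE2V2 91.8 against 94.1 CPM, in sgCEBPD against sgControl. PRKDC, the catalytic subunit of DNA-dependent protein kinase, and MCM4, a subunit of the replicative helicase, stood at 671 and 379 CPM in sgCEBPD 3 against control means of 1433 and 795 CPM. CEBPA was at 154 against 119 CPM (adjusted p = 0.401 in edgeR), CEBPB at 40.8 against 33.5 CPM and CEBPE at 20.6 against 22.4 CPM. In sgCEBPD 3, CEBPB stood at 60.6 and CEBPE at 35.5 CPM, and without it the means were 34.5 against 33.7 CPM for CEBPB and 15.7 against 22.5 CPM for CEBPE (log2 fold change -0.51, adjusted p = 0.207 in edgeR, no overlap between the groups). CEBPG (105 against 104 CPM) and CEBPZ (69.8 against 74.3 CPM) differed by less than the SD of the sgCEBPD group. CEBPZ stood at 47.8 CPM in sgCEBPD 3, and without that library its means were 77.6 against 74.7 CPM, the other direction. DDIT3, which encodes CHOP, stood at 34.4 CPM in sgCEBPD 3 and at 3.09 to 5.36 CPM in the other sgCEBPD libraries.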

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

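The tests on sgCEBPD 3 were chosen after its position was seen, except the test of its share of same-direction genes against split controls, which was set out before that result was computed. Among the groups of 4 values examined, 11 held a library far from the other 3, where chance alone gives about 1 in 20, or 5.1. In 7 of them the library was sgCEBPD 3, but A2M, SPP1, ATP1B1 and BPI were named from the comparison without it, which favours genes alike in the other sgCEBPD libraries, so the 1 in 20 does not hold for them. Its first component score was 96.0 against -13.4 to 0.57 in the other sgCEBPD libraries. PRKDC stood at 671 CPM (others 1413 to 1558), DDIT3 at 34.4 (3.09 to 5.36), A2M at 69.2 (3.74 to 6.05), SPP1 at 162 (11.2 to 31.6), ATP1B1 at 35.3 (4.82 to 6.05) and BPI at 17.6 (0 to 0.346). Among controls, sgControl 4 was apart for SPP1 at 4.86 CPM (others 2.91 to 3.00), ZNF467 at 3.12 (6.18 to 6.30) and ROS1 at 12.1 (4.72 to 5.68), and sgControl 2 for ADGRG3 at 4.17 (4.81 to 4.86).

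That sgCEBPD 3 stands apart is not a matter of depth, since its total of 10712069 counts was within the range of the others and 39 genes with at least 30 counts in each other library had 2 or fewer there, against 0 in the highest of 100 Poisson draws. Loss of all of chromosome 8q beyond CEBPD is argued against by a median log2 ratio of -0.067 over 251 genes (95% bootstrap interval -0.13 to 0.01). Losing 1 copy of 4 gives -0.42. A shorter loss next to CEBPD was not tested. On that side, PRKDC and MCM4 stood in sgCEBPD 3 at 45.9% and 47.8% of the mean of the other libraries. UBE2V2, farther out, stood at 92.6%. PRKDC and MCM4 start side by side on opposite strands (at 47960183 and 47960185), so their levels may not be independent. G1/S genes were also lower as a list in sgCEBPD 3 (median log2 ratio -0.69 to the mean of sgCEBPD 1, 2 and 4). The levels of PRKDC, MCM4 and UBE2V2 therefore cannot decide on such a loss. Whether sgCEBPD 3 lacks the change seen in sgCEBPD 1, 2 and 4 (a wrong label) was tested by size, after seeing the data. Genes called against 1 pair of controls changed in the same sense in sgCEBPD 3 against the other pair. Signed medians were 0.34 to 1.19 (log2) over the 6 ways of splitting the controls (0.46 to 0.93 in sgCEBPD 1, 2 and 4). The upper bounds for matched random genes were 0.11 to 0.28. Random genes were matched on expression alone, not on spread or joint movement, so the size test cannot decide. The share of the called genes that moved in the same direction, the test set out beforehand, was 66.1% to 72.9%. In 2 of the 6 ways it only equalled the upper bound of random genes, which reached 68.8%. On the second principal component sgCEBPD 3 scored 7.47, within the range of the controls (5.60 to 21.6). Scores on the first and second components are uncorrelated by construction, and sgCEBPD 3 dominated the first. Its second score is therefore set by the scores of the other libraries and cannot decide on the label. Another cell line, a wrong label and an effect of this guide alone (1 library per guide) cannot be told apart here. For another line, the highest correlation was 0.931, with no value between lines to set it against. Medians of chromosomes 21, 22, 9, 5 and 3 were shifted by -0.19, -0.14, -0.09, 0.08 and 0.07. Their adjusted permutation p was 0.0125, 0.0125, 0.0167, 0.0281 and 0.0400. This permutation drew random genes within this single library and treats genes as independent, so p does not measure the spread between libraries. No other library was examined in this way, so the shifts cannot decide whether chromosomes differ. Growth from different founder cells, a candidate raised below for other libraries, was not tested for sgCEBPD 3.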

How the results depend on the processing

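Voom with quality weights and the second set of results without sgCEBPD 3 were added after seeing the data. The other settings, each of the 8 libraries left out included, were fixed before. With 8 libraries, 11 genes were called in edgeR. DESeq2 called 292, quality weights 223, no filter 20, 1 surrogate variable 302 and an adjusted p under 0.01 called 1, and leaving out 1 library gave 0 to 283. DESeq2, quality weights, no filter and the surrogate variable kept all 11. Without sgCEBPD 3, 283 genes were called, against 596 with DESeq2, 109 with 1 surrogate variable, 40 at an adjusted p under 0.01, 44 over a 1.2-fold bound and 66 to 312 with 1 more library left out. The cause was not tested, except that stricter thresholds call fewer genes by construction. Lists past camera were 10 with 8 libraries and 5 to 15 with 1 library left out. They were 5 without sgCEBPD 3, 8 there with no filter and 4 to 7 with 1 more left out. Both were 0 with an estimated correlation and 0 in the directional fry test, and 3 and 20 in the mixed one. Same-numbered libraries of both groups also carry the same number in their library names. Their deviations from the group means correlated at 0.03, 0.06, -0.08 and -0.04, and only the libraries numbered 2 correlated best with their own number. The sgCEBPD mean included sgCEBPD 3, which stands apart, so this check is weak and whether the numbers pair the libraries stays open. With the replicate block, 1 gene was called with 8 libraries. Without sgCEBPD 3 the block called 352 genes, 198 of them among the 283, and 9 lists. The CEBPD log2 fold change stayed negative and short of the threshold, at -0.41 to -0.12 with 1 library left out. Of the values for named genes with 8 libraries, 302 kept direction and call, 39 lost the call, 21 gained it and 12 turned direction. Without sgCEBPD 3, 437, 151, 0 and 25 did. Values that kept direction and call include genes not past the threshold in the main fit, which had no call to lose. No named gene past the threshold turned. With 8 libraries, the log2 fold change turned to 0.041 with quality weights and 0.063 with 1 surrogate variable for PRKDC, to 0.053 and 0.051 for CEBPZ, and to -0.012 and -0.010 for CEBPG, which also turned with library totals (-0.0080). With 1 library left out it ran from -0.25 to 0.068 for PRKDC, -0.51 to 0.089 for CEBPE, -0.0096 to 0.053 for CEBPG and -0.18 to 0.055 for CEBPZ. Without sgCEBPD 3, it turned for MCM4 with quality weights (0.0093), no filter (0.0012), the replicate block (0.016) and 1 surrogate variable (0.026), for CEBPB with the block (-0.022), and for DDIT3 with voom (-0.018), quality weights (-0.060), library totals (-0.0011) and the block (-0.064). With 1 more library left out it ran from -0.065 to 0.033 for MCM4, -0.030 to 0.012 for UBE2V2, -0.032 to 0.12 for CEBPB, -0.037 to 0.022 for CEBPG and -0.22 to 0.18 for DDIT3. With 10.2 to 11.5 counts behind 1 CPM, genes near 1 CPM rest on few counts.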

Other observations

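The tests below, other than those of other splits, were chosen after the result was seen. In sgCEBPD 3, a single library, 39 genes were off (2 counts or fewer, with 30 or more in each other library) and 50 were on in the same sense. No other library had more than 1 of either. IGF2BP1, an RNA-binding protein, had 0 counts against a mean of 127 CPM of library totals elsewhere, at least 454-fold lower with a floor of 3 counts, and CDKN2A, which encodes the cell cycle inhibitor p16, had 0 against 49.6 CPM. MTAP, the neighbour of CDKN2A, stood at 53.2% of the mean of the other libraries. TAL1, a transcription factor of blood progenitors, had 1 count. Genes on there included HIPK2 (63.6 CPM of library totals) and GPR27 (51.3). The genes named in this part were picked after their values were seen.

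Against the mean of sgCEBPD 1, 2 and 4, the fixed lists of inflammatory and NF-kB genes (median log2 ratio 0.99), late neutrophil maturation (0.89), immediate early genes (0.89), integrated stress and unfolded protein responses (0.81), monocyte and macrophage genes (0.73) and hypoxia and glycolysis (0.50) in sgCEBPD 3 lay above all of 10000 random lists matched on expression. G1/S genes (-0.69) and MYC and its targets (-0.65) lay below all of them. G2/M genes had a median of 0.01, at the 59.4th percentile. CXCL8 stood at 171 CPM against 21.9 to 75.4, PLAUR at 154 against 11.3 to 21.3, CDKN1A at 463 against 147 to 259 and MYC at 471 against 774 to 964 in the other 7 libraries. Each is a description of this library, with no replicate.

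Other libraries also held genes that were on in one and off in another. Over the 7 libraries without sgCEBPD 3, 65 genes had 2 counts or fewer in 1 library and 50 or more in another, against 0 in the highest of 100 Poisson draws, which argues against counting noise. SLC26A9 had 959 counts in sgControl 1 and 2 in sgControl 4, and AGAP1 had 464 in sgCEBPD 2 and 0 in sgControl 4. Among the 4 controls alone there were 28 such genes, which no guide against CEBPD can account for; for the rest that stays open. A candidate explanation is that each culture grew from different founder cells, and the 12 such genes among sgCEBPD 1, 2 and 4 cannot decide it, since no value for pools of many cells is at hand.

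Chance division of the libraries was tested by refitting other splits. Of the 35 splits of 8 libraries into 4 and 4, 1, the real one, called as many as 11 genes, and the highest of the others called 0. Of the 35 splits of the 7 libraries without sgCEBPD 3 into 3 and 4, 1, the real one, reached 283, and the highest of the others called 13. The real split called the most genes of the 35 in both comparisons, the strongest result that this number of splits allows. For the 8 libraries this argues against chance division alone. For the 7 libraries it cannot decide, since sgCEBPD 3 was left out after its values were seen.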
